A study of Mus musculus with 2 samples.

How the data were processed

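Monomethylation of lysine 4 of histone H3 (H3K4me1), a chromatin mark found at enhancers and beside active promoters, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in limb tissue of mouse embryos at embryonic day 13.5. Per the labels, the tissue came from pools of male and female B6NCrl embryos, and the 2 samples are biological replicates 1 and 2 from separate tissue collections; replicate 2 combined 2 technical runs. There was 1 group, with no control group, so no groups could be compared; values are given for each replicate and were not tested across the 2 replicates.

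The 4 peak lists deposited by the authors were used: 1 for each replicate, 1 called on the replicates pooled, and 1 of replicated peaks. Per the file headers, the peak lists were made on mm10, the list of replicated peaks was derived from the other 3 lists, replicate 1 peaks came from its filtered alignment and 1 further file, and replicate 2 peaks from its filtered alignment and 2 further files. The aligner, the peak caller, the threshold and the rule by which a peak was kept as replicated are not given in the sources used here. Each peak carries a score, deposited by the authors and by the narrowPeak format an enrichment value, and the authors' −log10 p and −log10 q. Whether the score is a ratio is not stated, so it was used only to describe, rank or filter peaks and to correlate the replicates. Peak lists hold no read counts, so the depth of each library is unknown and no counting interval was computed for a peak. A difference in the number of peaks between the replicates can come from depth, from the control or from the tissue.

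Coordinates are 1-based on mm10, and no peak lay beyond the end of a GRCm38 chromosome. Genes and transcription start sites (TSSs) came from GENCODE mouse release 21, with 21728 protein coding genes on the 19 autosomes and X. Promoters were 1 kb either side of a TSS of the basic annotation of coding and long non-coding genes, and base pairs were assigned in the order promoter, exon, intron, intergenic. Coverage around coding TSSs was computed in 100 bp bins over 5 kb either side. The value at the TSS is the mean of the bins within 200 bp, and flanks were searched within 3 kb. A percent of TSSs or positions covered is the mean over genes of the share of base pairs in peaks, not a count of genes. Promoters were called CpG-rich where the observed over expected CpG of the kb around the TSS was at least 0.6. That division was made after the data were seen.

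For each coding gene, the covered share was the percent of the window of 50 kb either side of its TSS that lay in peaks. Here and in the TSS profiles, that TSS was the outermost start of the annotated gene record, the longest record where a symbol repeats. The median of each of 21 gene lists was set against 10000 random lists of the same size, matched on the number of coding TSSs in the window (10 quantile bins, of which ties left 6), with a two-sided permutation p adjusted by Benjamini-Hochberg over the lists. The lists covered limb patterning and signalling genes, Hox genes, the cell types of the limb, cell types of other organs, housekeeping genes, and olfactory and vomeronasal receptors. The covered share of each of 28 regions was set against 10000 random placements of an interval of the same length. The smallest p these permutations can give is 0.0002. Genes are not independent replicates, so these p-values describe these libraries. For 17 motifs, matches per kb on either strand in the central 500 bp of replicated peaks over 5 kb from any TSS were divided by those in 500 bp windows 5 kb away that no pooled peak touched. Up to 20 letter permutations of each motif served as the control. Replicate peaks were compared at a minimum overlap of 1 bp and against 1000 circular shifts of replicate 2 along each chromosome, with a one-sided permutation p.

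The tests, lists, regions, motifs and most alternatives were fixed before the data were examined. The genes named are the 4 members of each list with the largest covered share and, in lists under 100 genes, every member with none; the 20 coding genes with the largest covered share; the nearest coding gene of the 10 widest and the 10 highest-scoring replicated peaks; and the 5 genes that differed most between replicates in each direction. Other named genes were chosen after their values were seen and are named as such. The alternatives fixed then were a q of at most 0.01, a score of at least 3, other overlaps, promoter widths, windows and flanks, counts in place of coverage, other random lists and placements, and each replicate alone. Alternatives added after the data were seen were replicated peaks that overlap a peak of both replicates, 1 gene per 100 kb locus, autosomal genes only, random lists matched on promoter CpG content in place of TSS density or together with it, letter permutations with the same CpG number, absent peaks at the lowest score, and each replicate alone for peaks per chromosome.

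The list tests, the permutation p, and the overlap, coverage and motif counting functions were tested on simulated data. The circular shifts, annotation classes, TSS profiles and region placements were not. Of 200 simulated lists of 20 genes among the 21728 genes, the median test called 62.5% at an unadjusted p under 0.05 when the covered share was multiplied by 2, 89.5% when multiplied by 3, and 7% of unchanged lists. The overlap function found 6986 of 6986 shared peaks among 10000 simulated peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. One list member, Ahsp, was not matched to the annotation, and 1 pooled peak off the assembled chromosomes was left out.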

Results

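H3K4me1 was mapped in embryonic day 13.5 mouse limb, from mixed-sex pools, in 2 biological replicates. Replicate 1 gave 225713 peaks over 118.7 Mb and replicate 2 gave 243919 peaks over 134.3 Mb. The authors' list of replicated peaks held 159741 peaks with a median width of 661 bp, which covered 146.3 Mb or 5.55% of the assembly. Peak scores in that list ran from 1.48 to 12.8, and read depth is unknown. Values below are for replicated peaks, with those of replicates 1 and 2 beside them where the comparison rests on them.

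The widest replicated peak was in Dab2ip and the highest-scoring in Ncor2. A peak of 34.2 kb lay in Dab2ip, which encodes a Ras GTPase-activating protein (chromosome 2, 35667401 to 35701563), and replicate 1 covered 97.7% of it and replicate 2 97.5%. Next in width were peaks of 21.9 kb at Smad7, an inhibitor of TGF-beta signalling, 20.9 kb in Igsf3, 18.9 kb in Bahcc1 and 18.6 kb in Cxxc5. Capzb, Ahdc1, Zmiz1, Ncor2 and Zfhx3 held the other 5 of the 10 widest, with 15.6 to 18.1 kb; the peak in Zfhx3 had Pmfbp1 as its nearest coding TSS. The highest score, 12.8, was at Ncor2, a nuclear receptor corepressor (chromosome 5, 125145398 to 125161693), followed by Dab2ip at 11.7 and by Ryk, a Wnt receptor, at 11.5. Zmiz1, Nfatc1, Ctdsp2, Sept9, Tcf20 and Pxn held the next peaks, with 10.9 to 11.5, and the tenth, with 10.8, overlapped no coding gene and lay 60.6 kb from the TSS of Rpusd4. The peak in Sept9 had Gm11733 as its nearest coding TSS. Of the replicated peaks, 879 were over 5 kb wide.

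Peaks of the separate tissue pools fell at the same places more often than shifted peaks did. A peak of replicate 2 overlapped 76.6% of replicate 1 peaks, and the reverse share was 67.7%. Circular shifts gave a median of 9.16% and at most 9.99% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The overlap rose with the score of the replicate 1 peak, from 57.9% in the lowest quintile to 98.6% in the highest. Across 136980 replicated peaks with a score in both replicates, which are not independent replicates, Spearman's rho of the scores was 0.607 and Pearson's r was 0.702. Over coding genes, rho of the covered share within 50 kb of the TSS was 0.990. Ebf3, Sema4c, Smad3, Clmn and 1700122O11Rik had the largest excess in replicate 2, and Zc2hc1b, Ech1, Ltv1, Fam84b and Cbx3 the largest excess in replicate 1. Smad3, which encodes a transducer of TGF-beta signals, was covered over 46.7% of its window in replicate 1 and 55.1% in replicate 2, and Ech1, a peroxisomal enzyme, over 20.7% and 17.7%. At a reciprocal overlap of 50%, the shared share of replicate 1 peaks was 45.1%.

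Introns held most of the marked sequence and promoters were the most enriched class. Introns took 55.7% of peak base pairs against 40.1% of the genome, a ratio of 1.39. Promoters took 11.2% against 2.75%, a ratio of 4.06, with 4.07 in replicate 1 and 3.94 in replicate 2. Exons had a ratio of 1.32 and intergenic sequence one of 0.542. The median peak lay 18.4 kb from the nearest TSS, and 71.2% of peaks lay over 5 kb from any TSS.

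H3K4me1 dipped at the TSS of CpG-rich promoters and did not dip at that of CpG-poor ones, most of which were not covered. At 10054 CpG-rich promoters, 12.0% of TSSs were covered, against 65.4% of positions 1150 bp downstream and 42.1% of positions 750 bp upstream. At 11674 CpG-poor promoters, 20.5% of TSSs and 20.6% of the highest flank were covered. A peak lay within 5 kb of 96.1% of CpG-rich and 49.2% of CpG-poor promoters. Over all coding genes the TSS was covered at 0.415 of the level of the highest flank, with 0.375 in replicate 1 and 0.410 in replicate 2.

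The gene lists differed in how their TSSs were marked. Housekeeping genes, such as Actb and Eef2, were covered at 11.4% of TSSs and at 69.5% of positions 1650 bp downstream, a ratio of 0.164, with 0.149 in replicate 1 and 0.142 in replicate 2. Surface ectoderm and epidermis genes were covered at 76.3% of TSSs, with 63.9% in replicate 1 and 67.2% in replicate 2. The TSSs of Grhl2 and Grhl3, which encode epithelial transcription factors, of Cdh1, the epithelial cadherin, and of Irf6 were covered in full, while those of Krt14 and Sp8 were not covered. Osteoblast genes had 57.02% of TSSs covered, neuron genes 56.0%, endothelium genes 55.0%, chondrocyte genes 49.1%, skeletal muscle genes 48.4% and limb mesenchyme transcription factors 43.7%. Of the remaining lists, intestine genes had 40.5%, with 19.9% in replicate 1 and 36.6% in replicate 2. Erythroid genes had 22.8% and heart muscle genes 18.4%. Hepatocyte genes had 8.26%, macrophage and leukocyte genes 6.67%, with 1.58% in replicate 1 and 6.50% in replicate 2 and all of it at Laptm5, olfactory receptor genes 0.230% and vomeronasal receptor genes 0. The genes named in this comparison were chosen after their values were seen, and the lists were tested against CpG-matched genes only as an added comparison.

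**Figure D1:**
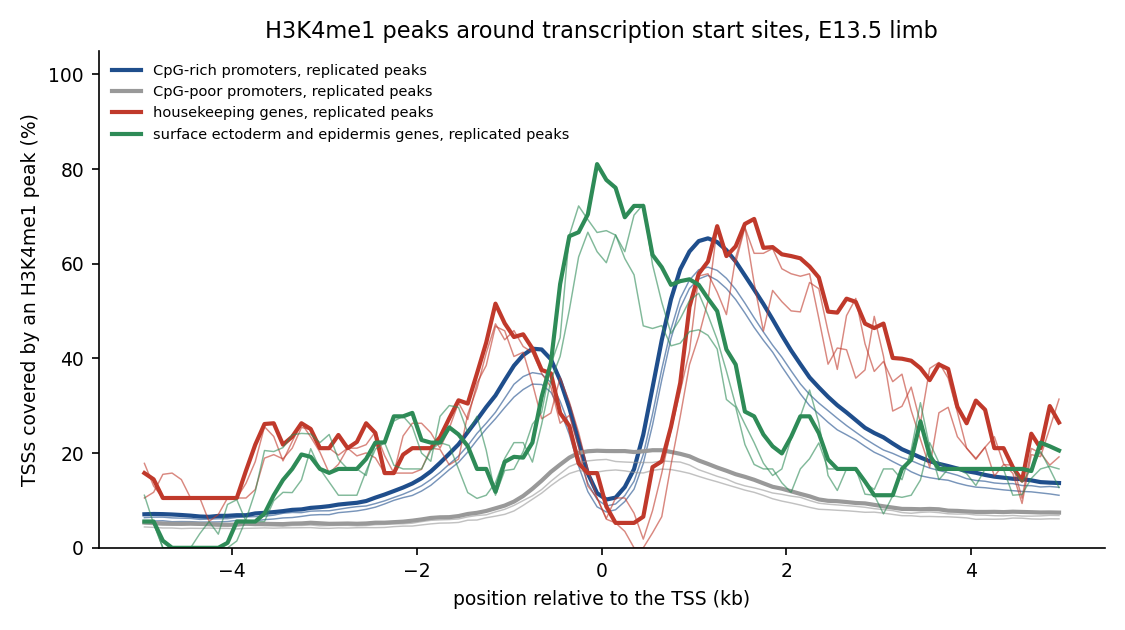
Percent of TSSs covered by an H3K4me1 peak (vertical axis) against the position relative to the TSS in kb (horizontal axis), for CpG-rich and CpG-poor promoters, housekeeping genes, and surface ectoderm and epidermis genes. Thick lines are replicated peaks and thin lines of the same colour are replicates 1 and 2; housekeeping genes fall to 11.4% at the TSS, and ectoderm and epidermis genes reach 76.3%.

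Genes that pattern the limb were more densely marked than matched genes. All 34 limb mesenchyme patterning transcription factors exceeded the median of all coding genes, 5.94%, with a list median of 19.6% against 4.53% in matched random lists. The list median was 15.1% in replicate 1 and 16.4% in replicate 2. The highest members were Lmx1b, which specifies dorsal limb identity, with 49.1% (ENSMUSG00000038765.13, chromosome 2, 33560965 to 33640511), Prrx2 with 47.4%, the hindlimb regulator Tbx4 with 44.1% and Tbx15 with 38.7%. Limb signalling genes had a median of 13.8% against 4.45%, led by Ptch1, the Hedgehog receptor, with 40.3%, Bmp7 with 37.5%, Wnt5a with 33.6% and Fgfr1 with 31.2%; 18 of 24 exceeded the median of all genes. Posterior HoxA and HoxD genes, which pattern the limb segments, had a median of 37.7% against 13.6%, led by Hoxa9 with 48.9%, Hoxa10 with 44.2%, Hoxa11 with 44.1% and Hoxd10 with 38.4%. HoxC genes had 31.1% against 11.8%, led by Hoxc6 with 34.2%, Hoxc8 with 33.8%, Hoxc9 with 32.0% and Hoxc5 with 31.8%. The annotated Hoxc5 record runs from 102967443 to 103017429, across Hoxc9, Hoxc8 and Hoxc6, so the TSS used for it lies beside that of Hoxc10. Each of these 4 lists exceeded its matched random lists at an adjusted permutation p of 0.0007, the smallest reached over the 21 lists, in the replicated list and in each replicate alone. HoxB genes, with a median of 13.3% against 10.9%, did not pass the test (adjusted permutation p = 0.734); Hoxb5, Hoxb4, Hoxb6 and Hoxb7 had 13.8 to 16.0%. With 1 gene per locus, the posterior HoxA and HoxD genes, at 2 loci, still passed (adjusted permutation p = 0.00504). That pass rests on 2 genes with a median of 40.9%, and the HoxA gene kept, Hoxa9, is the most covered of the list. The 9 HoxC genes lie at 1 locus, so only Hoxc13 was left, the least covered of them with 12.5%, and it did not pass (0.893).

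Among the differentiated cell types of the limb, cartilage, tendon and muscle genes were more densely marked than matched genes. Chondrocyte genes had a median of 10.96% against 4.75% (adjusted permutation p = 0.0126), with Pth1r, the receptor of parathyroid hormone-related protein, at 36.9%, Runx3 at 32.7%, Comp at 32.6% and the cartilage collagen Col2a1 at 29.7%. Tendon and joint genes had 14.6% against 4.71% (adjusted permutation p = 0.0096), with Fmod at 32.4%, Wnt9a at 28.2%, the tendon regulator Scx at 23.8% and Osr2 at 23.7%. Skeletal muscle genes had 10.96% against 4.77% (adjusted permutation p = 0.0159), with Mymk, which drives myoblast fusion, at 32.4%, Chrna1 at 26.3%, Des at 22.5% and Tnnt1 at 18.1%. Osteoblast genes did not pass, with 11.5% against 5.39% (adjusted permutation p = 0.0843); Dlx3 had 26.5%, Col1a1 25.5%, Sp7 23.6% and Col1a2 17.7%, and Phex, on X, had none. Surface ectoderm and epidermis genes did not pass, with 9.49% against 5.03% (adjusted permutation p = 0.0843); Grhl3 had 30.3%, Sp6 25.2%, Krt8 16.7% and Tfap2a 15.7%. With random lists matched on promoter CpG content in place of TSS density, the cartilage, tendon and muscle lists did not pass (adjusted permutation p of 0.164, 0.0815 and 0.172), though they did with both matched (0.0257, 0.0120 and 0.0257). The tendon and muscle genes failed in a 100 kb window (0.120 and 0.0912) and as numbers of peaks (adjusted permutation p of 0.208 and 0.0588), cartilage and muscle genes failed against unmatched lists (0.0854 and 0.0974), while ectoderm genes passed in a 20 kb window (0.0122) and osteoblast genes as numbers of peaks (0.0282).

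Lists of blood, vessel, nerve and other-organ cell types were not above matched genes, though single members were densely marked. Endothelium genes had a median of 5.87% against 5.53%, with the vessel regulators Erg at 31.4% and Eng at 30.5%, Esam at 19.2% and Egfl7 at 16.6%. Macrophage and leukocyte genes had 6.38% against 6.67%, with Laptm5 at 27.5%, Fcer1g at 21.97%, Cd68 at 20.0% and Aif1 at 12.3%, and none at Adgre1. Schwann cell and melanocyte genes had 6.42% against 5.34%, with Ngfr, a neurotrophin receptor, at 52.95%, Sox10 at 13.5%, Pmel at 11.6% and Mpz at 10.9%, and none at Tyr and Plp1. Neuron genes had 6.03% against 5.16%, led by Slc17a7, Neurod2, Eomes and Rbfox3 with 12.7 to 18.1%. Heart muscle genes had 5.85% against 5.66%, led by Myl7, Tnni3, Tnnt2 and Myh6 with 11.3 to 21.8%. Intestine genes had 4.78% against 5.40%, led by Cdx1, Lgals4, Lgr5 and Vil1 with 10.8 to 25.6%, and none at Sis. Hepatocyte genes had 3.57% against 5.75%, led by Foxa3, Apoh, Hnf1a and Tat with 9.47 to 16.7%, and none at Afp and Cyp7a1. The adjusted permutation p of these 7 lists ran from 0.377 to 0.940. Housekeeping genes had 11.6% against 7.07% (adjusted permutation p = 0.136), led by Rplp0, Hsp90ab1, Eef2 and Tubb5 with 25.4 to 34.8%, and passed in windows of 20 kb (0.0084) and 100 kb (0.0234) and with autosomal genes only (0.0328).

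Sensory receptor families and red blood cell genes had the lowest list medians. Of 1134 olfactory receptor genes, 961 had no peak within 50 kb of the TSS, and of 330 vomeronasal receptor genes, 302 had none. Their medians of 0 compared with 8.79% and 5.35% in matched random lists, each at an adjusted permutation p of 0.0007 and with a median of 0 in either replicate. Olfr71, Olfr70, Olfr159 and Olfr221 had 12.2 to 18.0%, and Vmn1r1, Vmn1r233, Vmn1r188 and Vmn1r231 had 4.36 to 6.56%. Erythroid genes had a median of 1.96% against 8.48% (adjusted permutation p = 0.0458). No replicated peak lay within 50 kb of the beta-globin genes Hbb-bt, Hbb-bs, Hbb-bh1 and Hbb-y or of Alas2, which makes heme, while Nfe2 had 39.6%, Epor 13.97%, Klf1 13.3% and Slc4a1 10.96%. The erythroid list did not pass with 1 gene per locus (adjusted permutation p = 0.256), with autosomal genes only (0.0554), as numbers of peaks (0.226) or against unmatched lists (0.111). With 1 gene per locus its median was 3.195%, above the 2.844% of hepatocyte genes. Against lists matched on promoter CpG content in place of TSS density, none of the 3 lists passed (adjusted permutation p of 0.159, 1 and 1 for olfactory, vomeronasal and erythroid genes), nor did the vomeronasal and erythroid lists with both matched (1 and 0.703).

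**Figure D2:**
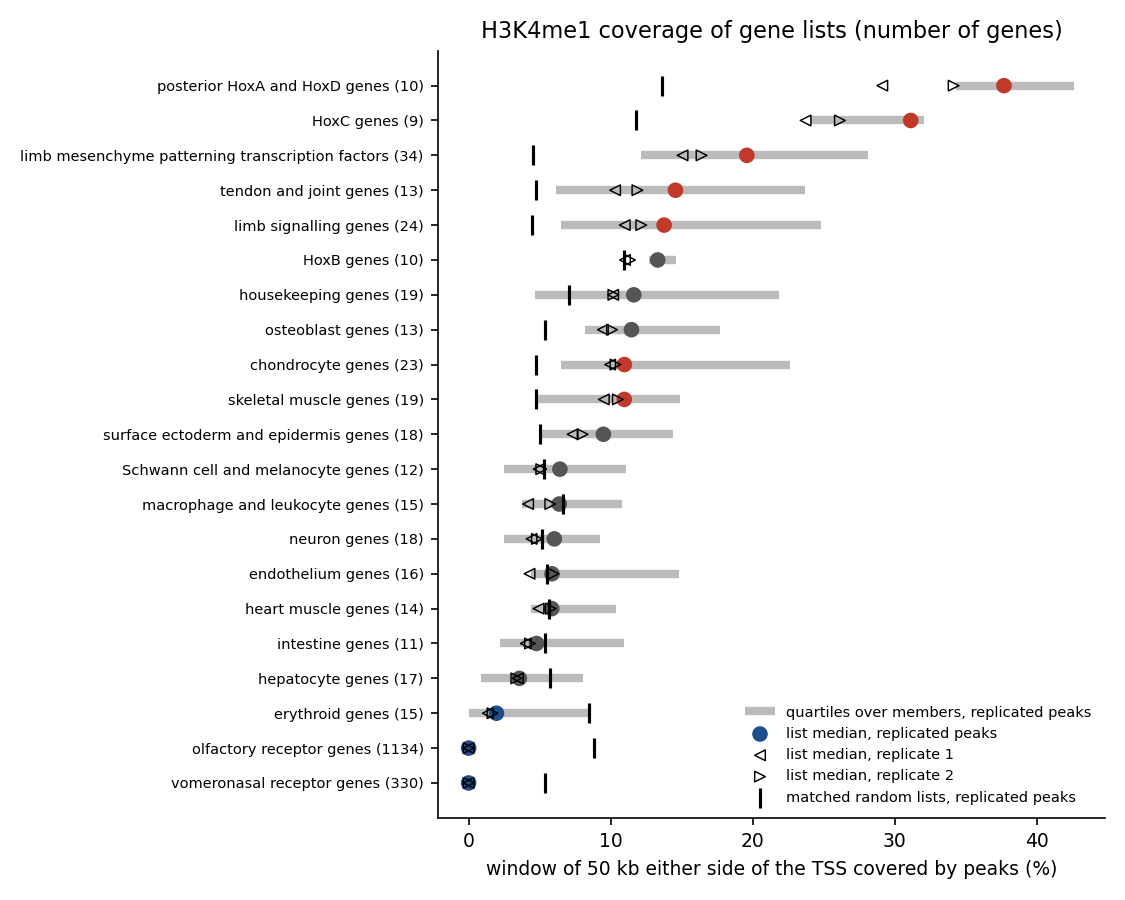
Percent of the window 50 kb either side of the TSS covered by H3K4me1 peaks (horizontal axis) for the 21 gene lists (vertical axis, number of genes in parentheses). Filled points are list medians in replicated peaks, red where above and blue where below matched random lists at an adjusted permutation p under 0.05; grey bars are quartiles over members, triangles the medians of replicates 1 and 2, and black ticks the median of random lists, so that posterior HoxA and HoxD genes at 37.7% lie farthest to the right.

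Among all coding genes, the largest covered shares were at G430095P16Rik with 69.4%, Mrpl23 with 69.2%, Lyl1 with 62.4%, Ski, a corepressor of TGF-beta signalling, with 62.4%, and Nxn with 61.8%. Ncor2, Nfix, Synpo, Tnnt3, Dusp7, Tcf20, Flrt1, Igsf3, Med13l, Prdm16, Smad3, Gse1, Actrt2, Timm22 and Ccdc33 completed the 20 highest, with 56.0 to 61.1%. Neighbouring genes share parts of their windows, as Mrpl23 and Tnnt3 do on chromosome 7 and G430095P16Rik, Lyl1 and Nfix on chromosome 8. No peak lay in the windows of 3659 genes, 16.8% of the total.

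The HoxA cluster was the most densely marked of the 28 regions. Peaks covered 52.8% of it (chromosome 6, 52155590 to 52260880), against a median of 2.40% over random placements, with 44.98% in replicate 1 and 48.5% in replicate 2. These placements were not matched on TSS number, and the HoxA cluster holds 13 coding TSSs. For the HoxA, HoxC and HoxD clusters, placements with a like number of TSSs were too few to compare. Gli3, which encodes the Hedgehog effector of digit patterning, was covered over 39.8%, Prrx1 over 38.7%, the HoxD cluster over 37.5%, the HoxC cluster over 31.4%, the Pitx1 to H2afy interval over 29.0% and the gene desert from Sox9 to Slc39a11 over 26.9%. These 7 regions lay between the 98.0 and 99.7 percentiles of placements, and 7 of 28 had an unadjusted permutation p under 0.05. None passed after adjustment over the regions, the smallest adjusted permutation p being 0.123 in the replicated list, 0.120 in replicate 1 and 0.115 in replicate 2. Counted as peaks per Mb, 2 regions passed, Gli3 (adjusted permutation p = 0.0112) and Prrx1 (0.0448).

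The intervals beside HoxD were marked on either side of the cluster. Of the centromeric interval, 16.1% was covered by 134 peaks, and of the telomeric interval 16.3% by 155 peaks. The strongest peak of the centromeric interval, with a score of 6.37, lay at 74189233 to 74192008 and that of the telomeric interval, with 6.08, at 75422463 to 75424333. The interval 5-prime of HoxA had 12.1%, Tbx5 to Tbx3 21.8%, Fgf8 to Fbxw4 19.9%, Tbx3 to Med13l 12.4%, Runx2 and Supt3 12.0%, HoxB 11.7%, Meis2 10.5% and Meis1 10.3%. Kcnj2 to Sox9 had 7.53%, with a peak of score 7.95 at 112620266 to 112623152 on chromosome 11. Lower shares were found at Grem1 and Fmn1 with 5.98%, Epha4 to Pax3 with 4.74%, Bmp2 to Hao1 with 3.89% and Trp63 with 3.77%. Of regions chosen for other tissues, the alpha-globin cluster had 7.98%, the fibrinogen cluster 1.11% and Foxg1 to Prkd1, beside a forebrain regulator, 0.261%, while the beta-globin cluster and the albumin and alpha-fetoprotein genes had no peak.

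The interval from Shh to Lmbr1 held 14 peaks over 1.51% of its 921.6 kb, at percentile 33 of random placements, whose median was 3.97%, so it was not apart from them (adjusted permutation p = 0.880). Of these, 4 lay within 10 kb of the TSS of Shh, the Hedgehog ligand of the posterior limb bud. A further 2 lay in intron 5 of Lmbr1, the intron known to hold a limb enhancer of Shh, at 29313855 to 29314226 and at 29314340 to 29315547 on chromosome 5. Their scores were 3.15 and 3.06, and replicate 1 covered 74.7% and 59.6% of them and replicate 2 93.0% and 92.3%. They lay 846.8 and 847.7 kb from the TSS of Shh, and were singled out after the values were seen.

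**Figure D3:**
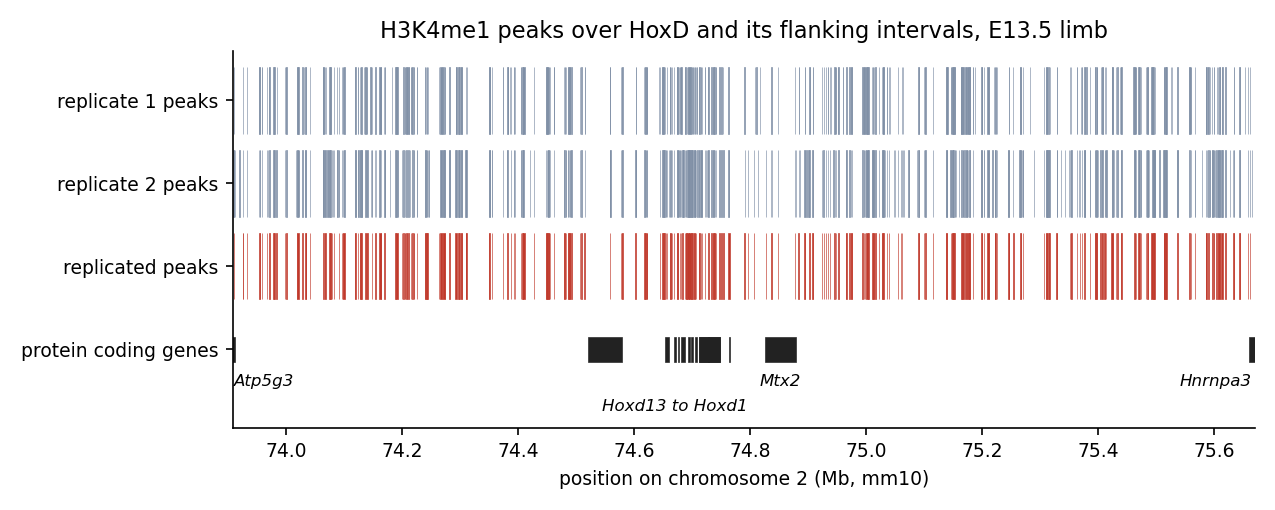
Peaks of replicate 1, replicate 2 and the replicated list, and protein coding genes (rows), along chromosome 2 in Mb of mm10 (horizontal axis), from Atp5g3 to Hnrnpa3. Replicated peaks cover 37.5% of the HoxD cluster in the middle and 16.1% and 16.3% of the intervals to its left and right.

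Distal peaks were enriched in homeodomain, basic helix-loop-helix, TEAD and AP-1 sequences relative to shuffled forms of the same motifs. The posterior Hox core TTTATGG occurred 0.189 times per kb in 113661 distal peaks against 0.150 in flanks, a ratio of 1.26, where the highest of its 20 letter permutations reached 0.987. The E-box CAGCTG, bound by myogenic and other basic helix-loop-helix factors, had a ratio of 1.86 against at most 1.72, the TEAD core GGAATG 1.24 against at most 1.13, and the AP-1 site TGAGTCA 1.13 against at most 1.12. The homeobox core TAATTA was less frequent in peaks than in flanks, with a ratio of 0.851, yet above its 13 permutations, which reached at most 0.766. These 5 of 17 motifs exceeded all their permutations, where chance would give 0.838; in replicate 1 alone the AP-1 site did not and the CTCF core did. The E-box CATATG lay below all its permutations, with a ratio of 0.698 against at least 0.720. Meis, T-box, GLI, SOX, RUNX, GATA, p53-family, HNF4, CTCF, SRF and NFY motifs lay within the range of theirs. The CTCF core, with 47 matches in peaks, and the SRF motif, with 52, were too rare to rank.

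**Figure D4:**
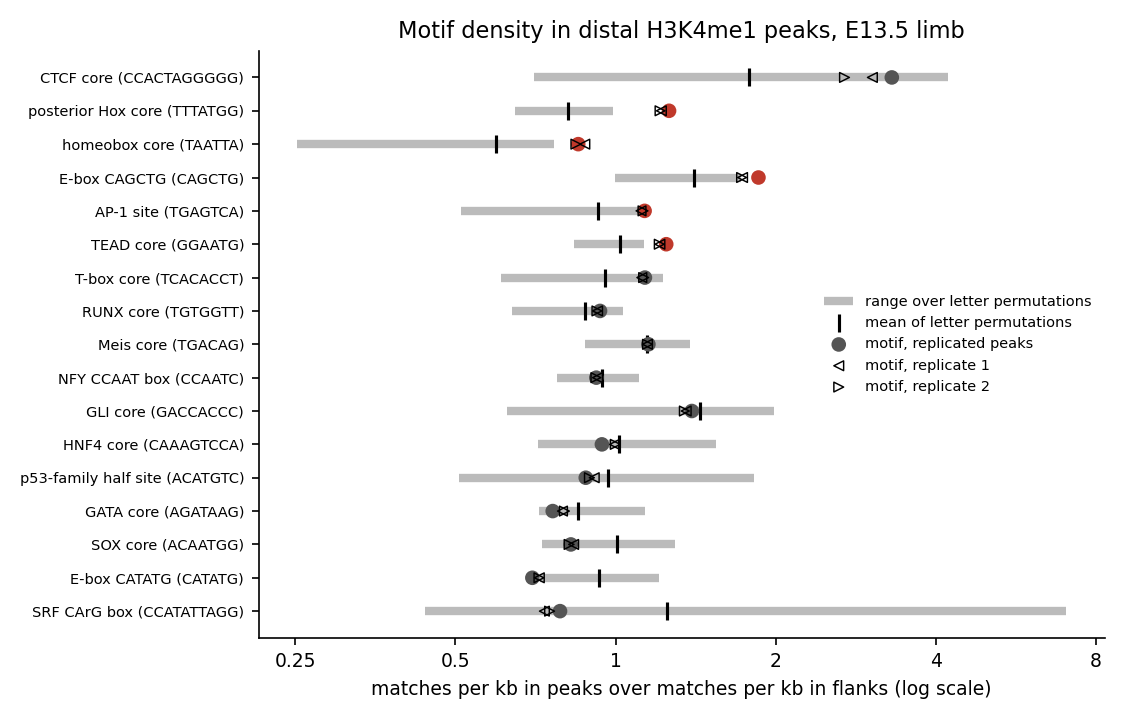
Ratio of motif matches per kb in distal peaks to those in flanks (horizontal axis, log scale) for the 17 motifs (vertical axis). Filled points are replicated peaks, red where above all letter permutations; triangles are replicates 1 and 2, grey bars the range and black ticks the mean of the permutations, and the posterior Hox core at 1.26 lies above its range.

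The X chromosome carried few peaks. It had 6.92 replicated peaks per Mb against 66.2 on the autosomes, a ratio of 0.105, with 0.106 in replicate 1 and 0.115 in replicate 2. Chromosome 14 had the lowest density of the autosomes, 54.7 per Mb, and chromosome 11 the highest, 89.2. A peak lay within 5 kb of the TSS of 27.3% of X-linked coding genes and of 72.9% of autosomal ones. X-linked list members with no peak in their window included Phex, Alas2 and Plp1.

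**Figure D5:**
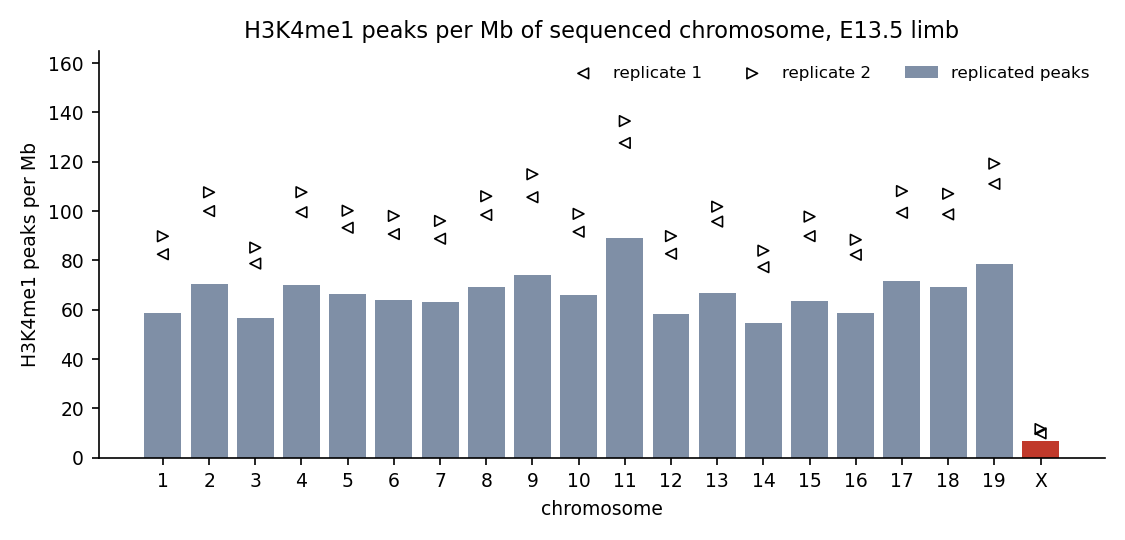
H3K4me1 peaks per Mb (vertical axis) by chromosome (horizontal axis). Bars are replicated peaks and triangles are replicates 1 and 2; the bar of X, in red, stands at 6.92 and those of the autosomes between 54.7 and 89.2.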

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

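The comparison of the pooled list with the other lists was chosen after the result was seen. All 159741 replicated peaks are rows of the pooled list, so values for replicated peaks rest on intervals called on the pooled replicates. The full pooled list entered no comparison of gene lists or regions. It held 101280 peaks outside the replicated list. Of these, 1054 overlapped a peak of each replicate by at least 1 bp, and they are 1.04% of such peaks. The peaks of the 2 replicates need not overlap each other there, and the authors' rule for a replicated peak is not given. Conversely, 22761 replicated peaks, 14.2%, did not overlap a peak of both replicates, and 798 overlapped a peak of neither. Those 22761 had a median width of 382 bp and a median score of 2.62, against 744 bp and 3.41 for the rest. With 2 replicates, no test for an outlying sample was possible.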

How the results depend on the processing

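Results were recomputed under the alternatives set for each, and no call reversed, though some lists without a call changed sign, such as HoxB genes (differences from −0.509 to 7.31). Of 251 recomputations of single gene lists, 227 stayed on the same side of the threshold, 19 lost and 5 gained a call; of 162 of single regions, 160 stayed and 2 gained. Of 119 motif ratios 67 moved, of 18 ratios of annotation classes 9, and of 68 main values 18. Placements with a like number of coding TSSs were too few for 6 regions. These were the HoxA, HoxB, HoxC, HoxD, alpha-globin and beta-globin clusters, which were set only against placements not matched on TSS number. Removing replicate 1 or replicate 2 changed no list or region call. With promoter CpG content matched in place of TSS density, an alternative added after the data were seen, 4 in place of 7 lists were above and 0 in place of 3 below. With both matched, also added, 7 lists were above and 0 below of the 20 that could be drawn, so CpG matching ended no call of a higher list while TSS density stayed matched. Olfactory receptor genes could not be drawn with both matched. Counted as peaks per Mb, 2 in place of 0 regions were above. A score of at least 3 kept 96890 of 159741 peaks. The shared percent of replicate 1 peaks, 76.6, became 67.2 with 50% of the peak covered and 45.1 with reciprocal 50%, as stricter overlaps must lower it. With a q of at most 0.01 in both lists it became 75.2. The score correlation of 0.607 became 0.569 over 2 kb from a TSS, 0.648 with −log10 p, and 0.561 with absent peaks at the lowest score. The promoter ratio of 4.06 was 4.17 in peaks overlapping both replicates, 3.41 with 2.5 kb promoters and 3.94 to 4.07 in single replicates. The TSS ratio of 0.415 was 0.581 over all annotated genes and 0.375 to 0.410 in single replicates. The X to autosome ratio of 0.105 was 0.0962 in peaks overlapping both replicates and 0.106 to 0.115 in single replicates. Where no reason is given, the cause was not tested. Depth is unknown, so a place without a peak may hold H3K4me1 below the authors' threshold, and the replicated list, at 159741 peaks, cannot show it.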

Other observations

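The comparisons of gene families, of TSS coverage against matched genes and of X-linked promoters were chosen after the data were seen. For fewer X copies, X repeats and the limb lists other than with both matched, the outcome that would count against each explanation was also written only after its value was seen. Among 310 families of coding genes that share a symbol stem and at least 8 loci, each counted once per locus, 17 were above and 11 below random lists matched on TSS density. The Smad genes, transducers of TGF-beta and BMP signals, had a median covered share of 27.1% against 4.54% (8 loci, adjusted permutation p = 0.0113), with Smad3, Smad7, Smad6 and Smad1 highest. The T-box genes had 18.99% against 5.50% (12 loci), the Wnt genes 18.3% against 4.66% (15 loci), the semaphorins 16.3% against 5.63% (20 loci) and the tetraspanins 15.3% against 5.68% (20 loci). These 5 families also passed against random lists matched on promoter CpG content in place of TSS density. The collagens, with 10.7% against 4.76% (42 loci), the Frizzled receptors, with 14.9% against 4.66% (10 loci), and the integrin alpha chains, with 16.4% against 5.41% (12 loci), passed on TSS density alone. Cytochrome P450 genes, at 0.502% against 4.98% (66 loci), secretoglobins, prolactin-family genes, serpin B genes, claudins, sulfotransferases and keratin-associated proteins were below, and none of these 7 was below CpG-matched lists. The Btbd family was below under both, but 24 of its 37 loci lie on X.

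Several lineage lists, though not all, stood out at the TSS. Against random lists matched on promoter CpG content, 7 of 10 lineage lists had more of the TSS covered, which argues against CpG content as the whole account. The lists were ectoderm and epidermis (76.3% against 23.3%, adjusted permutation p = 0.0014), osteoblast, chondrocyte, skeletal muscle, endothelium, neuron, and Schwann cell and melanocyte genes; tendon and joint (36.8% against 21.8%), erythroid (22.8% against 13.8%) and macrophage and leukocyte genes (6.67% against 15.5%) did not pass. With the covered share within 50 kb matched as well, in 5 bins, 6 of the 10 lists still passed. These bins are coarse and leave marking closer to the TSS unmatched. The comparison therefore cannot decide whether dense marking around the gene accounts for those 6. Chondrocyte genes, at 49.1%, lost the call as random lists rose from 24.7% to 31.4% (adjusted permutation p = 0.0649). Neuron genes, though not above matched genes within 50 kb, had 56.0% against 24.4% (adjusted permutation p = 0.0048). Outside the 10 lists, limb mesenchyme transcription factors passed both comparisons (43.7% against 20.2%, adjusted permutation p of 0.00315 and 0.0277). Limb signalling genes passed only the first (adjusted permutation p of 0.016 and 0.0851), and the Hox lists passed neither. Housekeeping genes, at 11.4% against 16.2%, were not apart from CpG-matched genes (adjusted permutation p = 0.539). Intestine genes, a list for another organ, had 40.5% against 17.1% (adjusted permutation p = 0.0543), but 19.9% in replicate 1 alone. No biological explanation was tested.

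The density of H3K4me1 at limb gene lists may come from how the genes lie in the genome. Several genes of 1 locus counted separately are not the whole account for limb mesenchyme transcription factors and muscle genes. With 1 gene per locus, 32 of 34 and 17 of 19 were kept, and both lists passed (adjusted permutation p of 0.00105 and 0.0131). The 24 limb signalling, 23 chondrocyte and 13 tendon and joint genes each lay at separate loci. Their lists were unchanged, so the repeat was no test for them and the explanation does not apply. The posterior HoxA and HoxD genes also passed with 1 gene per locus, but that pass rests on 2 genes. Hoxa9, 1 of them, is the most covered of the list, so the pass may depend on the member kept. For HoxC genes the explanation cannot be told apart, because they lie at 1 locus and the gene kept, Hoxc13 with 12.5%, is the least covered. CpG content of the promoters is argued against as the whole account: with CpG content matched in place of TSS density 4 of the 7 lists passed, and with both matched all 4 patterning lists and all 3 differentiation lists did. With both matched the cartilage list median exceeded random lists by 5.70 percentage points, the tendon list by 9.60 and the muscle list by 6.28, against 6.21, 9.85 and 6.19 with TSS density alone. No biological explanation was tested, since the series holds 1 tissue and 1 age.

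Few peaks on X could reflect a lower X dose in mixed-sex pools. Even with male embryos alone, the pooled libraries would hold at least as many X reads per Mb as the shallower replicate holds per autosomal Mb. The pooled list had 13.7 peaks per Mb of X against at least 77.3 on any autosome of either replicate. That comparison matches the number of reads alone. Pooling does not raise X reads relative to autosomal reads, and the caller, threshold and control are not known here. It therefore cannot decide whether a lower X dose accounts for the few peaks. Unplaceable repeats are argued against as the whole account, as the X to autosome ratio per unmasked Mb was 0.131, where the lowest autosome stood at 0.843. Gene content was tested at CpG-rich promoters, of which 56.3% on X and 90.3 to 99.3% on single autosomes had a peak within 5 kb. A control library with another X dose than the H3K4me1 libraries cannot be told apart from a chromatin difference of X, because no control reads were analysed here to set beside the ratio of 0.105. The X-linked genes with the largest covered share were Bcor, a transcriptional corepressor, with 25.6%, and Gpc3, a regulator of growth, with 23.2%.

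Nfe2, the most densely marked erythroid gene, lies on chromosome 15 at 103248212 to 103258403. The HoxC cluster ends at 103036852 on that chromosome, outside the 50 kb window of Nfe2, and no link between them was tested. The Shh gene had 7.27% of its window covered, against a median of 5.94% over all coding genes.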
